A study of Homo sapiens with 28 samples.

How the data were processed

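Poly(A) RNA of BEAS-2B cells was sequenced after 2 h of treatment with vehicle, RNO at 1 µM, salmeterol at 0.3, 0.5 or 100 nM, or RNO with salmeterol at 0.3 or 0.5 nM, in 4 libraries per group. Per the labels' protocols, cells were held in serum-free medium overnight before treatment, RNA was column-purified, libraries were directional, and they were sequenced on a NextSeq instrument over a pair of sequencing kits; which kit a library was in is not labelled. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.18.0.12 and quantified with kallisto and sleuth, for which no version is given, and the builds are named as GRCh37 and hg19.

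The authors deposited 1 table with 28 columns of signal, the authors' normalized TPM per gene symbol. Its column totals run from 967478 to 1024770 rather than to a single total, which is how TPM look after division by a factor per library. It was checked that each of the 16350 symbols is above 0 in at least 15 of the 28 libraries; 75 entries join more than 1 symbol. TPM keep no read counts, so the depth of each library, and the counting error of each value, are unknown. Median-of-ratios size factors computed from the table lay between 0.996 and 1.01.

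Values were taken as log2(TPM + 1). The 13016 genes with at least 1 TPM in at least 4 libraries were tested with limma 3.58.1 in R 4.3.3 (group means, empirical Bayes with trend), with all 28 libraries in 1 fit (21 residual degrees of freedom) and 16 comparisons, each two-sided with Benjamini-Hochberg adjustment within the comparison. An adjusted p under 0.05 was called, without a limit on the fold. An interaction is the combination minus both single treatments plus vehicle. These comparisons, the filter, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined; the response index, the contrast of what RNO added at 0.3 and 0.5 nM, the sign flips of the index differences over replicates, and the fits without Salm0.3 replicate 4 with the block or for the lists were added after that.

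Genes were named by this rule: for each treatment against vehicle, the 10 largest increases and 5 largest decreases among called genes with a mean of at least 1 TPM and all 4 treated libraries on the same side of all 4 vehicle libraries; for the other comparisons 5 and 5 by the same criteria (for interactions the adjusted p and the mean only); per list up to 4 members with the smallest adjusted p; and always the genes of a fixed set, among them NR4A1, NR4A2, NR4A3, CREM, PDE4A, PDE4B, PDE4C, PDE4D, RGS2, DUSP1, CRISPLD2, PER1, FOS, FOSB, IL6, CXCL8 and AREG.

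Gene lists numbered 27 with 605 entries, of which 525 were in the file and 467 were tested; some genes, such as RGS2, DUSP1 and PER1, are in more than 1 list. They cover CREB targets, cAMP signalling, immediate early genes, cytokines, NF-κB feedback, glucocorticoid-responsive genes, MAPK feedback, EGFR ligands and receptors, YAP targets, TGF-β and matrix genes, circadian genes, cholesterol synthesis, G1/S, G2/M, p53 targets, the integrated stress response, hypoxia and glycolysis, interferon-stimulated genes, SOCS and JAK-STAT, epithelial, mesenchymal, immune, endothelial and ciliated or club cell markers, mitochondrially encoded genes, histones and ribosomal proteins. Sets were tested with camera (limma) at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, whose p asks whether a set moves one way on balance and whose mixed p asks for change in either direction; neither fry test compares the set with other genes.

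The labels number the replicates 1 to 4 in every group. The sample descriptions carry another set of numbers, repeated in the same order in every group. Nothing in the labels says what a number marks. Whether the numbers pair the libraries was checked from the data: the deviations from the group means correlated at 0.17 to 0.494 in the 84 pairs with the same number (median 0.31) and at -0.331 to 0.108 in the 252 other pairs (median -0.115), and 28 of 28 libraries correlated best with their own number. Since every same-number pair lay above 0.1, the numbers were taken to pair the samples. The fit with the number as a block (18 residual degrees of freedom) is given where it moves a count by more than 1.5 times. It is also given for some, not all, of the calls of named genes that it changes.

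Both fits were tested on simulated data with the residual spread and the replicate effects per gene of all 28 libraries and changes added to the Salm100 group. Of 100 genes shifted by 0.5 on the log2 scale, 89 were recovered without the block and 92 with it, and of 100 shifted by 1, 97 and 98; 1 and 8 unchanged genes were called. For RNO against vehicle, to which no change was added, 1.15% of p-values lay under 0.05 without the block and 5.03% with it, so the fit without the block was conservative here. Camera at its preset correlation called 2 of 460 lists over 20 draws without an effect and without replicate effects. The genes were drawn independently of each other, so these draws could not test whether the preset correlation suits the data.

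The response index, its exact permutation tests, the splits of the libraries and the alternatives (pseudocounts of 0.1 and 5, no filter, size-factor scaling, the block, only the groups compared, robust limma, and leaving out each library) have their results in the report and the closing section. Values within groups were screened for outlying libraries with Dixon's ratio. Figures were drawn with matplotlib 3.10.9. All columns of the table were used.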

Results

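RNA-seq was used to measure transcript abundance in BEAS-2B cells, an established line of human airway epithelial cells, after 2 h of treatment. There were 28 libraries in 7 groups of 4: vehicle, 1 µM roflumilast N-oxide (RNO), salmeterol at 0.3, 0.5 or 100 nM (Salm0.3, Salm0.5, Salm100), and RNO together with 0.3 or 0.5 nM salmeterol (Salm0.3_RNO, Salm0.5_RNO). Salmeterol is a long-acting bronchodilator that raises cAMP; the labels call 100 nM maximal and the lower concentrations sub-maximal. RNO is the active metabolite of roflumilast and inhibits phosphodiesterase 4, the enzyme family that breaks down cAMP. The deposited table held normalized TPM per gene symbol, and 13016 genes were tested. Library totals lay between 967478 and 1024770 TPM; since TPM carry no read counts, the depth of each library is unknown. Between 12463 and 12673 genes reached 1 TPM in a library. The entry named MIR6723 took 24.1 to 25.6% of all TPM and the entry named MIR4461 5.81 to 6.73%. A share of TPM is not a share of reads, and which transcripts gave the reads of these entries was not tested. Salm0.3 replicate 4 listed 303 genes at 0, against 6 to 19 in each of the other 27 libraries. Changes below are on log2(TPM + 1), which understates the fold change of genes near or below 1 TPM. A value after ± is the SE of a log2 change or the SD of a level in TPM (n = 4 per group). Nothing in the labels says that the replicates came from separate cultures, so the p-values may measure only technical spread.

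The effect of maximal stimulation was read from 100 nM salmeterol against vehicle. The largest increase was in the orphan nuclear receptor gene NR4A3, from 0.611 ± 0.0694 TPM in vehicle to 62.9 ± 5.56 TPM (log2 change 5.31 ± 0.12, adjusted p = 7.41e-21). The long non-coding RNA LINC00473 followed, from 2.78 ± 0.816 to 81.5 ± 10.1 TPM (4.47 ± 0.14, adjusted p = 1.07e-17), and then NR4A2, of the same family as NR4A3, from 0.643 ± 0.0645 to 32.4 ± 5.68 TPM (4.33 ± 0.17, adjusted p = 3.86e-16). The zinc finger gene ZNF331 (3.95 ± 0.12) also rose, as did the genes of the secreted cytokines IL6 (3.88 ± 0.22) and IL11 (3.11 ± 0.17). So did those of the kinase SGK1 (3.67 ± 0.19), of RGS2 (3.25 ± 0.20), which speeds GTP hydrolysis by G proteins, of the membrane protein TM4SF1 (2.93 ± 0.11) and of the growth arrest protein GAS1 (2.91 ± 0.10). IL6 went from 3.47 ± 0.465 to 65.5 ± 11.1 TPM and SGK1 from 18.4 ± 3.54 to 244 ± 31.1 TPM. The largest decreases were in the AP-1 subunit gene FOSL1, from 153 ± 13.1 to 36.5 ± 7.29 TPM (-2.06 ± 0.17), the transcription factor genes KLF10 (-1.90 ± 0.24) and EGR1 (-1.88 ± 0.22), the G protein regulator RGS4 (-1.55 ± 0.25) and TXNIP (-1.47 ± 0.11), whose protein binds thioredoxin. For these 15 increases and decreases the highest adjusted p was 4.18e-05. In each, as the rule for naming genes required, all 4 treated libraries lay on the same side of all 4 vehicle libraries. Of the cAMP-degrading enzymes, PDE4D (2.47 ± 0.07) and PDE4B (1.44 ± 0.10) rose, and PDE4A (-0.006 ± 0.10) did not pass the test (adjusted p = 0.982). NR4A1 (2.69), DUSP1 (1.99), CRISPLD2 (2.88), PER1 (1.51), FOSB (1.38), FOS (0.55), CREM (0.36) and AREG (1.79) rose. PDE4C and CXCL8 were below the filter and were not tested. In all, 1110 genes rose and 1208 fell, which is 17.8% of those tested; 136 of the increases and 9 of the decreases were at least 2-fold. With the replicate number as a block, 2242 rose and 2359 fell.

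**Figure D1:**
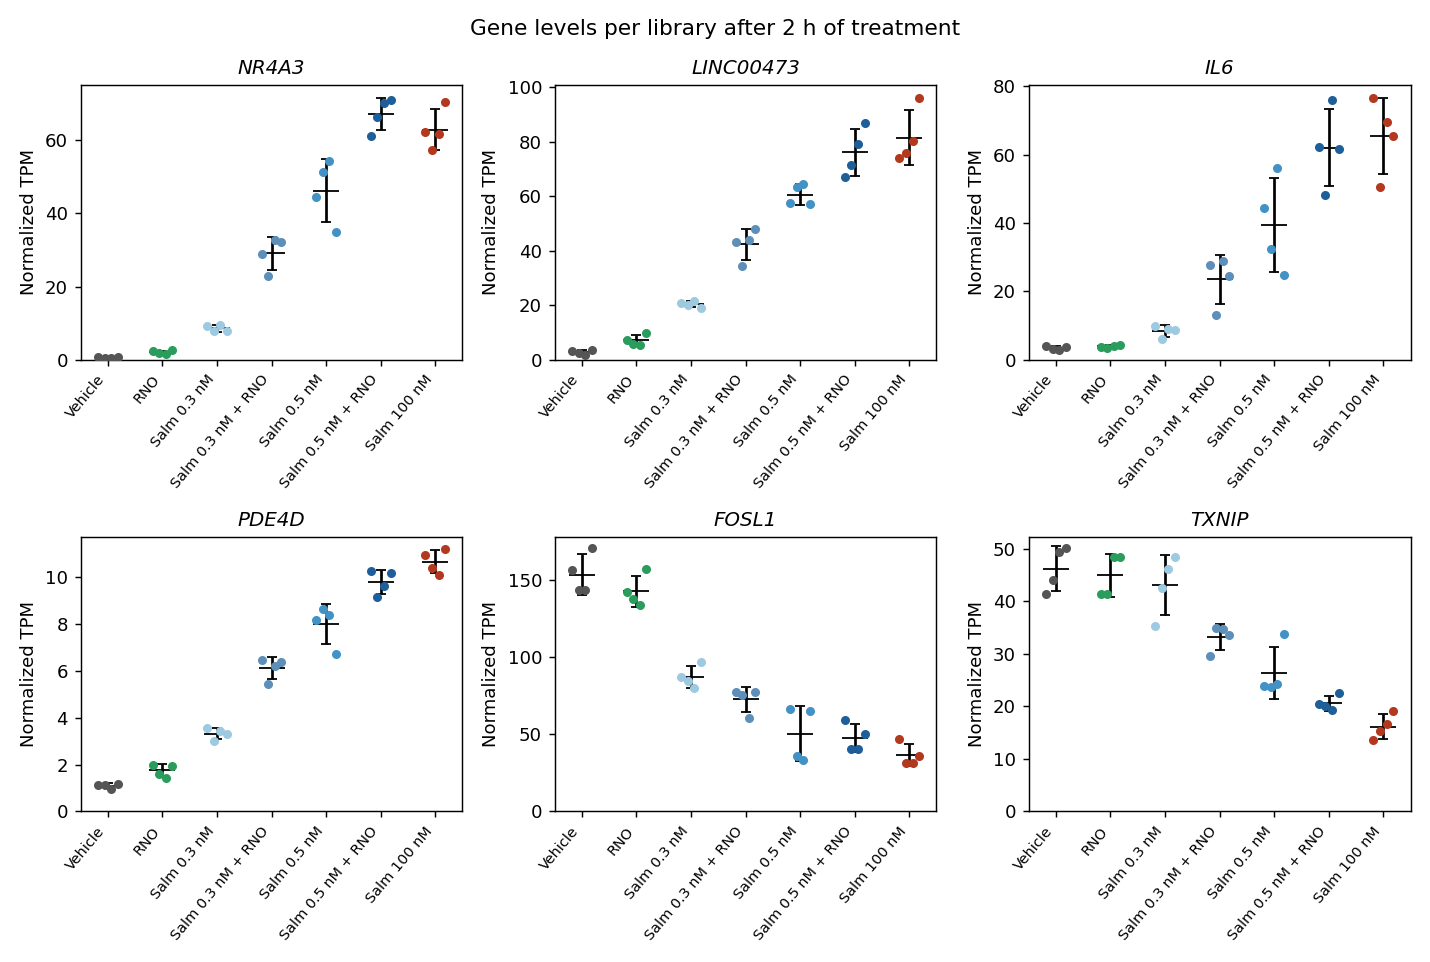
Normalized TPM of NR4A3, LINC00473, IL6, PDE4D, FOSL1 and TXNIP (vertical axes) in the 4 libraries of each of the 7 groups (points), with the group mean and SD (bars). NR4A3 averaged 0.611 TPM in vehicle and 62.9 TPM at 100 nM salmeterol.

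Gene lists fixed beforehand were read in the same comparison. Camera compares a list with the other tested genes at a preset correlation; camera calls given without a second value also held with an estimated correlation. Of the 26 tested targets of the cAMP-responsive factor CREB, 22 rose and 1 fell (22 and 1 adjusted over the list alone), among them NR4A3 (5.31), PDE4D (2.47), NR4A2 (4.33) and NR4A1 (2.69). The CREB target list had a median log2 change of 1.41, camera up with adjusted p = 9.61e-32. Among 40 components of cAMP signalling, 8 rose and 2 fell (8 and 2 adjusted over the list alone, 13 and 4 with the replicate block), the increases led by PDE4D, the kinase anchor AKAP12 (1.83), RGS2 and PDE4B, of which the phosphodiesterases and RGS2 limit the pathway. The cAMP signalling list had a median log2 change of 0.059, camera up with adjusted p = 0.00115, adjusted p = 0.0555 with an estimated correlation. Of 19 glucocorticoid-responsive genes, 11 rose and 0 fell (12 and 1 adjusted over the list alone), among them CEBPD (1.93), SGK1 (3.67), RGS2 (3.25) and CRISPLD2 (2.88), although no glucocorticoid was given. The glucocorticoid-responsive list had a median log2 change of 0.35, camera up with adjusted p = 4.8e-11. The 29 immediate early genes split: 14 rose and 9 fell (14 and 10 adjusted over the list alone), with NR4A1 (2.69), ATF3 (1.47), BTG1 (1.08) and MAFK among the increases and FOSL1, EGR1 and KLF10 among the decreases. The immediate early list had a median log2 change of 0.087, camera up with adjusted p = 0.0397, adjusted p = 0.719 with an estimated correlation, adjusted p = 0.108 with the replicate block.

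Among 17 cytokine and chemokine genes, 7 rose and 1 fell (9 and 1 adjusted over the list alone, 12 and 1 with the replicate block), including IL6 (3.88), IL11 (3.11), CCL2 (1.18) and IL24 (1.16). The cytokine list had a median log2 change of 0.27, camera up with adjusted p = 1.8e-07. Of 21 NF-κB feedback and innate genes, 8 rose and 0 fell (8 and 1 adjusted over the list alone, 10 and 3 with the replicate block), including REL (1.41), BCL3 (1.19), PTGES (0.97) and NFKBIZ (0.87). The NF-κB feedback list had a median log2 change of 0.10, camera up with adjusted p = 0.000874, adjusted p = 0.0857 with an estimated correlation. Of the 18 SOCS and JAK-STAT genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone). The SOCS and JAK-STAT list had a median log2 change of 0.041, camera up with adjusted p = 0.0129, adjusted p = 0.0857 with an estimated correlation. SOCS3 (1.93 ± 0.14), an inhibitor of cytokine signalling, SOCS5 (0.41) and the receptor gene IL6R (0.92) rose, and the survival gene MCL1 (-0.43) fell. Of 21 interferon-stimulated genes, 2 rose and 0 fell (1 and 0 adjusted over the list alone, 2 and 3 with the replicate block), the increases being the exonuclease gene ISG20 (1.35) and ISG15 (0.76 ± 0.25), a call lost without any one of Salm100 replicate 1 or 3 or Vehicle replicate 1 or 2 (adjusted p from 0.0726 to 0.144) and when only the groups compared were fitted (adjusted p = 0.0505; 0.00771 to 0.144 over all alternatives). The interferon list had a median log2 change of 0.25, camera up with adjusted p = 0.0728. MAPK negative feedback genes went both ways: of 17, 5 rose and 7 fell (5 and 7 adjusted over the list alone), with the phosphatase genes DUSP1 (1.99) and DUSP8 (1.09) up and DUSP6 (-0.99) and SPRED1 (-0.26) down. The MAPK feedback list had a median log2 change of -0.055, mean 0.034, camera down with adjusted p = 0.666, the median and the mean differing in sign. Of 8 genes of EGFR ligands and receptors, 2 rose and 1 fell (3 and 1 adjusted over the list alone, 5 and 2 with the replicate block), the increases being the ligands AREG (1.79) and EPGN (0.85). The EGFR list had a median log2 change of 0.11, camera up with adjusted p = 0.0318, adjusted p = 0.282 with an estimated correlation, adjusted p = 0.0976 with the replicate block.

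The mitotic genes moved in a single direction: of 24 G2/M genes, 0 rose and 19 fell (0 and 23 adjusted over the list alone), among them PLK1 (-0.52), CENPA (-0.57), CCNB1 (-0.34) and TPX2 (-0.29). The G2/M list had a median log2 change of -0.21, camera down with adjusted p = 5.81e-16. Of 22 G1/S genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone, 8 and 2 with the replicate block), including the phosphatase gene CDC25A (0.31) and RRM2 (0.26), but also CDKN1A (0.64), an inhibitor of the cycle, while the cyclin gene CCND1 (-0.58) fell. The G1/S list had a median log2 change of 0.02, camera up with adjusted p = 0.164. Among 19 p53 targets, 4 rose and 4 fell (5 and 4 adjusted over the list alone), with TNFRSF10B (0.52), PLK2 (1.16) and CDKN1A (0.64) higher and GADD45A (-0.83) lower. The p53 target list had a median log2 change of -0.006, mean 0.058, camera up with adjusted p = 0.575, the median and the mean differing in sign. Of 9 replication-dependent histone genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone), HIST2H2BE (0.29 ± 0.072), a call that was lost when only the groups compared were fitted (adjusted p = 0.0638; 0.00216 to 0.0638 over all alternatives). The histone list had a median log2 change of 0.084, camera up with adjusted p = 0.306. Of 28 cytosolic ribosomal protein genes, 0 passed the limma test (1 at an unadjusted p under 0.05, 0 higher and 0 lower adjusted over the list alone, 8 and 0 with the replicate block). The ribosomal protein list had a median log2 change of 0.026, camera up with adjusted p = 0.127, adjusted p = 0.0116 with the replicate block.

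In the integrated stress response list of 18 genes, 9 rose and 4 fell (11 and 4 adjusted over the list alone), where HERPUD1 (0.88), ATF3 (1.47) and SLC7A5 (0.98) rose, and PPP1R15A (-0.85 ± 0.082), which ends the response, fell. The stress response list had a median log2 change of 0.19, camera up with adjusted p = 0.000874. Of 18 hypoxia and glycolysis genes, 9 rose and 0 fell (9 and 1 adjusted over the list alone), including the glucose transporters SLC2A3 (1.59) and SLC2A1 (0.36), ANKRD37 (1.32) and the glycolytic regulator PFKFB3 (0.69). The hypoxia and glycolysis list had a median log2 change of 0.12, camera up with adjusted p = 2.03e-06. Of 24 cholesterol synthesis genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone, 12 and 3 with the replicate block), including INSIG1 (0.51), which is not a synthesis enzyme but restrains the pathway. The cholesterol synthesis list had a median log2 change of 0.072, camera up with adjusted p = 0.0767, adjusted p = 0.00591 with the replicate block. Among 18 circadian genes, 4 rose and 3 fell (4 and 4 adjusted over the list alone), with PER1 (1.51) and NFIL3 (0.97) higher and the repressors BHLHE41 (-0.56) and CIART (-0.60) lower. The circadian list had a median log2 change of -0.062, mean 0.068, camera up with adjusted p = 0.999, the median and the mean differing in sign.

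YAP and TEAD targets went both ways: of 23, 6 rose and 5 fell (6 and 5 adjusted over the list alone, 9 and 8 with the replicate block), with LATS2 (1.79), NUAK2 (0.94) and FJX1 (0.51) higher and GADD45A (-0.83) lower; LATS2 encodes a kinase that restrains YAP. The YAP target list had a median log2 change of 0.027, camera up with adjusted p = 0.159. Of 22 TGF-β and matrix genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone, 13 and 2 with the replicate block), including TGIF1 (1.38), PMEPA1 (1.15) and NOG (0.29), whose proteins restrain TGF-β or BMP signalling, and SNAI2 (0.90). The TGF-β list had a median log2 change of 0.15, camera up with adjusted p = 0.00307, adjusted p = 0.534 with an estimated correlation. Of 10 epithelial and mucosal genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone), with the claudin gene CLDN1 (0.36) and AQP3 (0.36) higher and KRT18 (-0.31) lower. The epithelial list had a median log2 change of 0.052, camera up with adjusted p = 0.915. Among 14 mesenchymal marker genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone, 6 and 1 with the replicate block), with the collagen gene COL3A1 (0.58) higher and TWIST1 (-0.55) lower. The mesenchymal list had a median log2 change of 0.017, camera up with adjusted p = 0.296. The remaining lists had too few tested genes for a set test. Of the immune cell markers 5 were in the file and 1 was tested, CD68 (0.03, adjusted p = 0.875), and of the ciliated and club cell markers 2 were in the file and 1 was tested, CAPS (-0.12, adjusted p = 0.351). Of the endothelial markers 7 were in the file and 0 were tested, and of the mitochondrially encoded genes 0 were in the file.

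Sub-maximal stimulation was read from the lower concentrations. At 0.3 nM salmeterol NR4A3 rose to 8.61 ± 0.959 TPM (2.57 ± 0.12, adjusted p = 2.07e-13) and LINC00473 to 20.4 TPM (2.52 ± 0.14, adjusted p = 1.03e-11). ZNF331 (1.93), NR4A2 (1.91), IL11 (1.51), TM4SF1, GAS1 (1.47), NR4A1 (1.43), SGK1 (1.36) and RGS2 (1.20) rose as well, as did the phosphodiesterase genes PDE4D (1.04) and PDE4B (0.78). FOSL1 (-0.81) and DUSP6 (-0.51) fell; DUSP6 encodes a phosphatase that acts on ERK. IL6 (1.06 ± 0.22) rose (adjusted p = 0.00523), a call lost with a pseudocount of 5 (adjusted p = 0.0734; 0.000121 to 0.0734 over all alternatives). The decreases of KLF10 (-0.90 ± 0.24, adjusted p = 0.0498) and EGR1 (-0.82 ± 0.22, adjusted p = 0.0463) lay near the threshold. KLF10 lost its call without any one of Salm0.3 replicate 1, 2, 3 or 4 or Vehicle replicate 1, 2, 3 or 4 (adjusted p from 0.0546 to 0.156), and EGR1 without any one of Salm0.3 replicate 2, 3 or 4 or Vehicle replicate 1, 2, 3 or 4 (adjusted p from 0.0689 to 0.156). With a library left out the changes ran from -0.98 to -0.82 for KLF10 and from -0.93 to -0.73 for EGR1, and over all alternatives the adjusted p ran from 1.49e-05 to 0.156 and from 7.58e-06 to 0.156. Both calls also ended without the filter, with a pseudocount of 0.1 and with robust limma. All the fits that ended these calls were without the replicate block. With the block, both KLF10 and EGR1 kept their calls. The largest fitted increase was in the small RNA entry mir-1281 (2.69 ± 0.71, adjusted p = 0.046), from 22.8 ± 16.2 to 93 ± 56.2 TPM, where Salm0.3 replicate 4 stood at 177 TPM, the other 3 at 57.2 to 69.2 TPM and Vehicle replicate 3 at 0. The call was lost without any one of Salm0.3 replicate 1, 2, 3 or 4 or Vehicle replicate 3 (adjusted p from 0.0543 to 0.184; 0.00984 to 0.51 over all alternatives). It was also lost without the filter, with a pseudocount of 0.1, with robust limma and with only the groups compared. Here 150 genes rose and 95 fell (61.2% higher), and 22 changed at least 2-fold. With the block 613 rose and 628 fell (49.4% higher). Among the 26 CREB targets, 12 rose and 0 fell (14 and 0 adjusted over the list alone), with a median log2 change of 0.31, camera up with adjusted p = 1.28e-23. In the G2/M list of 24 genes, 0 rose and 5 fell (0 and 7 adjusted over the list alone, 0 and 13 with the replicate block, 0 and 3 without Salm0.3 replicate 4), PLK1 (-0.23) among them, with a median log2 change of -0.069, camera down with adjusted p = 1.09e-09. Of 17 cytokine genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone), with a median log2 change of 0.12, camera up with adjusted p = 6.28e-05.

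At 0.5 nM salmeterol NR4A3 reached 46.3 ± 8.65 TPM (4.86 ± 0.12, adjusted p = 6.23e-20) and IL6 39.4 ± 13.7 TPM (3.12 ± 0.22, adjusted p = 5.07e-11). The other large increases were in LINC00473 (4.05), NR4A2 (3.97), ZNF331 (3.66), SGK1 (3.16), RGS2 (2.91), IL11 (2.76), TM4SF1 (2.61) and NR4A1 (2.57), and the largest decreases in FOSL1 (-1.65), KLF10 (-1.46), EGR1 (-1.34), RGS4 (-1.28) and JUN (-0.96). PDE4D (2.09), PDE4B (1.22), DUSP1 (1.69), CRISPLD2 (2.40), PER1 (1.43), FOSB (1.26) and AREG (1.36) rose. In total 649 genes rose and 600 fell, 86 and 4 of them at least 2-fold. With the block 1589 rose and 1626 fell. At 0.5 nM, of 26 CREB targets 20 rose and 0 fell (21 and 1 adjusted over the list alone), with a median log2 change of 1.22, camera up with adjusted p = 2.82e-37. Again no mitotic gene passed upward: of 24 G2/M genes, 0 rose and 15 fell (0 and 21 adjusted over the list alone, 0 and 23 with the replicate block), with a median log2 change of -0.15, camera down with adjusted p = 1.46e-16. Of 19 glucocorticoid-responsive genes, 9 rose and 0 fell (9 and 1 adjusted over the list alone), with a median log2 change of 0.19, camera up with adjusted p = 7.43e-11. Of 29 immediate early genes, 12 rose and 8 fell (13 and 10 adjusted over the list alone), with a median log2 change of 0.20, camera up with adjusted p = 0.0172, adjusted p = 0.656 with an estimated correlation.

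**Figure D2:**
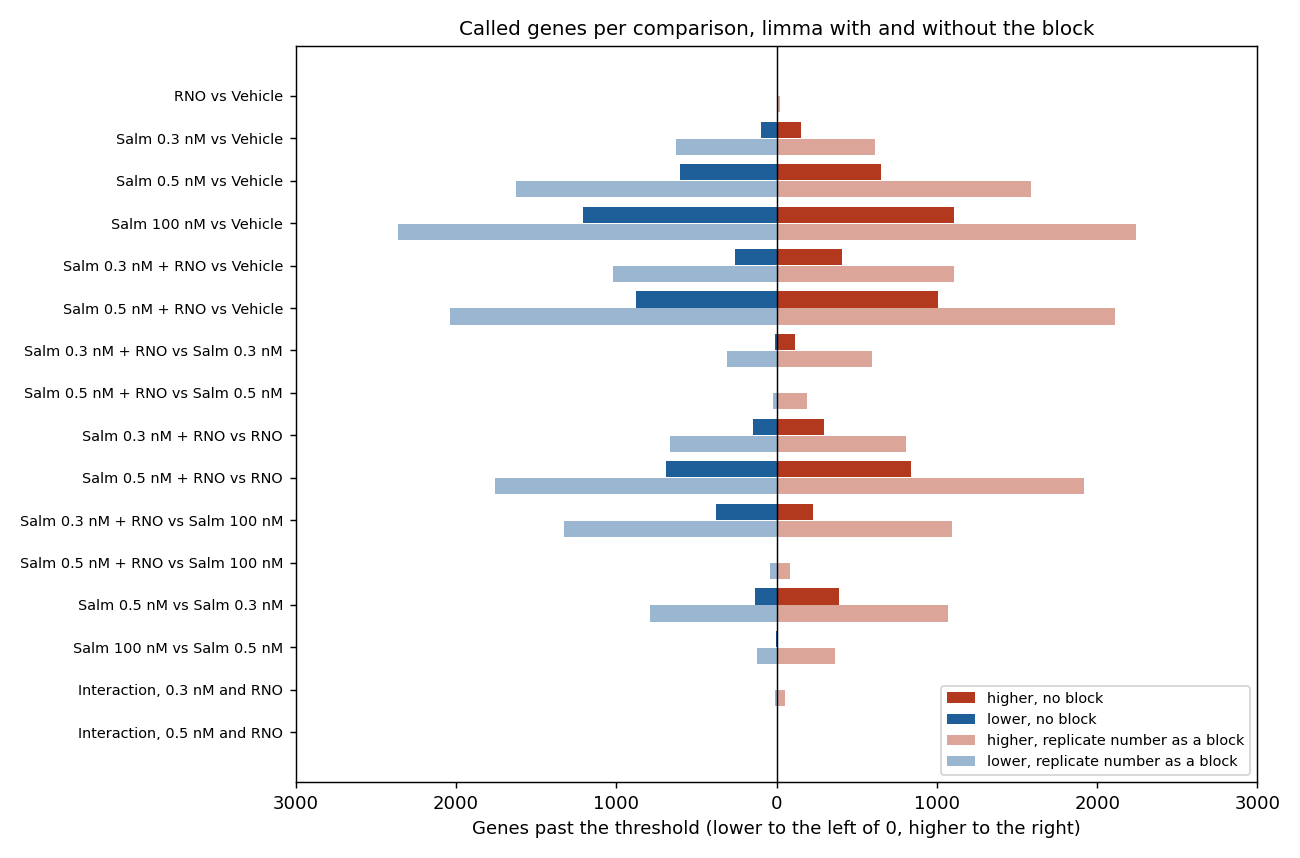
Number of genes higher (bars to the right of 0) and lower (bars to the left of 0) at an adjusted p under 0.05 in each comparison, without and with the replicate number as a block. Against vehicle, 245 genes passed at 0.3 nM salmeterol, 1249 at 0.5 nM and 2318 at 100 nM without the block.

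The step between concentrations was tested directly. From 0.3 to 0.5 nM, NR4A3 (2.28 ± 0.12), NR4A2 (2.06 ± 0.17), IL6 (2.05 ± 0.22), SGK1 (1.80 ± 0.19) and ZNF331 (1.73 ± 0.12) rose further (highest adjusted p 3.96e-07), and TXNIP (-0.69), JUN (-0.54) and the centriole gene HYLS1 (-0.48) were lower. FOSL1 was also lower (-0.85 ± 0.17), a call lost when only the groups compared were fitted (adjusted p = 0.106; 2.3e-05 to 0.106 over all alternatives). In this step 388 genes were higher and 136 lower (74.1% higher); with the block 1067 and 788 (57.5% higher). In this step, of 26 CREB targets, 17 rose and 0 fell (19 and 0 adjusted over the list alone), with a median log2 change of 0.83, camera up with adjusted p = 3.71e-39. Of the G2/M genes, 24 in number, 0 rose and 4 fell (0 and 8 adjusted over the list alone, 0 and 23 with the replicate block), with a median log2 change of -0.097, camera down with adjusted p = 3.86e-11.

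From 0.5 to 100 nM, 10 genes were higher and 2 lower. The facilitative glucose transporter gene SLC2A3 (0.32 ± 0.064) was higher (adjusted p = 0.0485), a call lost without any one of Salm100 replicate 1, 2 or 4 or Salm0.5 replicate 3 or 4 (adjusted p from 0.0643 to 0.234). It was also lost when only the groups compared were fitted (adjusted p = 0.779; 0.023 to 0.779 over these settings). PDE4D (0.38 ± 0.07, adjusted p = 0.0485), the kinase gene ITPKB (0.45 ± 0.087) and the galactosyltransferase gene B4GALT1 (0.35 ± 0.057) were higher and TXNIP (-0.67 ± 0.11, adjusted p = 0.0192) lower. PDE4D lost its call without any one of Salm0.5 replicate 1 or 4 or Salm100 replicate 1, 2 or 4 (adjusted p from 0.0632 to 0.231) and ITPKB without any one of Salm0.5 replicate 1, 3 or 4 or Salm100 replicate 1, 2 or 4 (adjusted p from 0.0643 to 0.282). B4GALT1 lost it without any one of Salm0.5 replicate 4 or Salm100 replicate 1, 2 or 4 (adjusted p from 0.0541 to 0.141) and TXNIP without any one of Salm0.5 replicate 4 or Salm100 replicate 1 or 2 (adjusted p from 0.0541 to 0.141). With only the groups compared these 4 calls ended as well (adjusted p = 0.779 for each), and those of PDE4D and ITPKB also ended without the filter and with a pseudocount of 0.1. Over all alternatives the adjusted p ran to 0.779 from 0.00162 for PDE4D, 0.000587 for ITPKB, 0.000322 for B4GALT1 and 3.14e-05 for TXNIP. The count was 0 without Salm100 replicate 1, Salm100 replicate 2 or Salm0.5 replicate 4, 1 without Salm100 replicate 4, 3 without Salm0.5 replicate 1, 23 without Salm0.5 replicate 2 and 19 without Salm0.5 replicate 3. At an unadjusted p under 0.05 there were 716 genes, and with the block 365 genes were higher and 125 lower; there NR4A3 (0.45 ± 0.12, adjusted p = 0.0313), CRISPLD2 (0.48 ± 0.089, adjusted p = 0.003) and IL6 (0.77 ± 0.16, adjusted p = 0.0092) were higher. Between these concentrations, of 26 CREB targets 1 rose and 0 fell (7 and 0 adjusted over the list alone, 9 and 0 with the replicate block, 0 and 0 without Salm0.3 replicate 4), with a median log2 change of 0.22, camera up with adjusted p = 2.42e-12, adjusted p = 0.0572 with an estimated correlation. Of 18 hypoxia and glycolysis genes, 1 rose and 0 fell (4 and 0 adjusted over the list alone, 5 and 0 with the replicate block, 0 and 0 without Salm0.3 replicate 4), namely SLC2A3, with a median log2 change of 0.07, camera up with adjusted p = 3.64e-07.

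RNO alone was compared with vehicle to read what phosphodiesterase 4 inhibition did without an agonist. Without a block 5 genes rose and 0 fell. LINC00473 went from 2.78 ± 0.816 to 7.07 ± 2.03 TPM (1.09 ± 0.14, adjusted p = 0.000447) and NR4A3 from 0.611 ± 0.0694 to 2.07 ± 0.413 TPM (0.92 ± 0.12, adjusted p = 0.000447). The transcription factor gene CEBPD rose from 34.6 ± 4.17 to 51 ± 5.73 TPM (0.55 ± 0.083, adjusted p = 0.00225), the lipid phosphatase gene PLPP3 from 10.4 ± 1.35 to 15.6 ± 1.66 TPM (0.54 ± 0.08, adjusted p = 0.00225). PDE4D, which encodes a target of the drug, rose from 1.1 ± 0.0949 to 1.75 ± 0.272 TPM (0.38 ± 0.07, adjusted p = 0.0288). PDE4D lost its call without any one of RNO replicate 1 or 4 or Vehicle replicate 1, 2, 3 or 4 (adjusted p from 0.0531 to 0.274). When only the groups compared were fitted, NR4A3 alone kept its call. LINC00473 (adjusted p = 0.355), CEBPD (0.355), PLPP3 (0.355) and PDE4D (0.648) lost it. With a pseudocount of 5 NR4A3 and PDE4D lost it (adjusted p = 1). That pseudocount lies above the levels of both genes in these groups and shrinks their changes, so this loss decides little about them. Over all alternatives the adjusted p ran from 5.04e-05 to 0.355 for LINC00473, 1.6e-07 to 1 for NR4A3, 9.9e-06 to 0.355 for CEBPD, 5.04e-05 to 0.355 for PLPP3 and 0.00148 to 1 for PDE4D. With the block 24 genes rose and 0 fell, adding IL11 (0.58 ± 0.082, adjusted p = 0.00101), NR4A1 (0.55 ± 0.091, adjusted p = 0.0075), CCL2 (0.43 ± 0.074, adjusted p = 0.0108), AREG (0.43 ± 0.088, adjusted p = 0.0406) and DUSP1 (0.41 ± 0.078, adjusted p = 0.0246). Leaving out RNO replicate 3 gave 8 genes. The limma test called NR4A2 (0.46 ± 0.17), PDE4B (0.29 ± 0.10), RGS2 (0.20 ± 0.20) and IL6 (0.13 ± 0.22) in neither fit. NR4A2 stood at 1.607 TPM in RNO replicate 1 and at 1.137 to 1.191 TPM in the other RNO libraries. All lay above its vehicle mean given earlier, so the missing call does not show that NR4A2 was unchanged. With RNO alone, of 26 CREB targets 2 rose and 0 fell (7 and 0 adjusted over the list alone, 5 and 0 with the replicate block), NR4A3 and PDE4D, with a median log2 change of 0.14, camera up with adjusted p = 1.89e-15, adjusted p = 0.0524 with an estimated correlation. Of the 24 G2/M genes, 0 passed the limma test (1 at an unadjusted p under 0.05, 0 higher and 0 lower adjusted over the list alone), with a median log2 change of -0.029, camera down with adjusted p = 0.00016, adjusted p = 0.117 with an estimated correlation. Of 17 cytokine genes, 0 passed the limma test (4 at an unadjusted p under 0.05, 2 higher and 0 lower adjusted over the list alone, 2 and 0 with the replicate block), with a median log2 change of 0.067, camera up with adjusted p = 1.71e-05, adjusted p = 0.0524 with an estimated correlation.

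The combinations were first compared with vehicle. With 0.3 nM salmeterol and RNO, NR4A3 stood at 29.1 ± 4.54 TPM (4.21 ± 0.12, adjusted p = 1.86e-18), NR4A2 at 17.4 ± 3.76 TPM (3.46 ± 0.17, adjusted p = 1.34e-13) and IL6 at 23.5 ± 7.23 TPM (2.40 ± 0.22, adjusted p = 1.2e-08). LINC00473 (3.54), ZNF331 (3.16), SGK1 (2.60), RGS2 (2.49), IL11 (2.37), NR4A1 (2.34) and TM4SF1 (2.21) completed the largest increases, and FOSL1 (-1.07) and JUN (-0.70) fell. In total 411 genes rose and 259 fell, and 54 of the increases and 1 decrease were at least 2-fold. With the block 1104 rose and 1023 fell. In this combination, of 26 CREB targets 18 rose and 0 fell (21 and 0 adjusted over the list alone), with a median log2 change of 0.92, camera up with adjusted p = 1.37e-44. From the G2/M list of 24 genes, 0 rose and 9 fell (0 and 14 adjusted over the list alone, 0 and 22 with the replicate block), with a median log2 change of -0.13, camera down with adjusted p = 2.91e-15. Of 18 genes of the integrated stress response, 5 rose and 3 fell (6 and 3 adjusted over the list alone, 10 and 4 with the replicate block), with a median log2 change of 0.071, camera up with adjusted p = 0.00432.

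With 0.5 nM salmeterol and RNO, NR4A3 stood at 67.2 ± 4.44 TPM (5.40 ± 0.12, adjusted p = 4.85e-21) and IL6 at 62 ± 11.3 TPM (3.80 ± 0.22, adjusted p = 7.1e-13). NR4A2 (4.56), LINC00473 (4.37), ZNF331 (4.08), SGK1 (3.68), RGS2 (3.38), IL11 (3.08), NR4A1 (3.00) and GAS1 (2.80) completed the largest increases, and FOSL1 (-1.69), RGS4 (-1.47), KLF10 (-1.36), EGR1 (-1.23) and TXNIP (-1.13) the largest decreases. The EGFR ligand genes AREG (1.75), EPGN (0.63) and HBEGF (0.33) rose. In total 1006 genes rose and 880 fell, 119 and 6 of them at least 2-fold; with the block 2111 rose and 2040 fell. Here, of 26 CREB targets, 22 rose and 0 fell (23 and 0 adjusted over the list alone), with a median log2 change of 1.43, camera up with adjusted p = 5.01e-39. The G2/M list had 24 tested genes, of which 0 rose and 16 fell (0 and 21 adjusted over the list alone), with a median log2 change of -0.18, camera down with adjusted p = 8.14e-14. Of 21 NF-κB feedback and innate genes, 8 rose and 0 fell (8 and 2 adjusted over the list alone, 11 and 3 with the replicate block), with a median log2 change of 0.097, camera up with adjusted p = 5.41e-05.

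**Figure D3:**
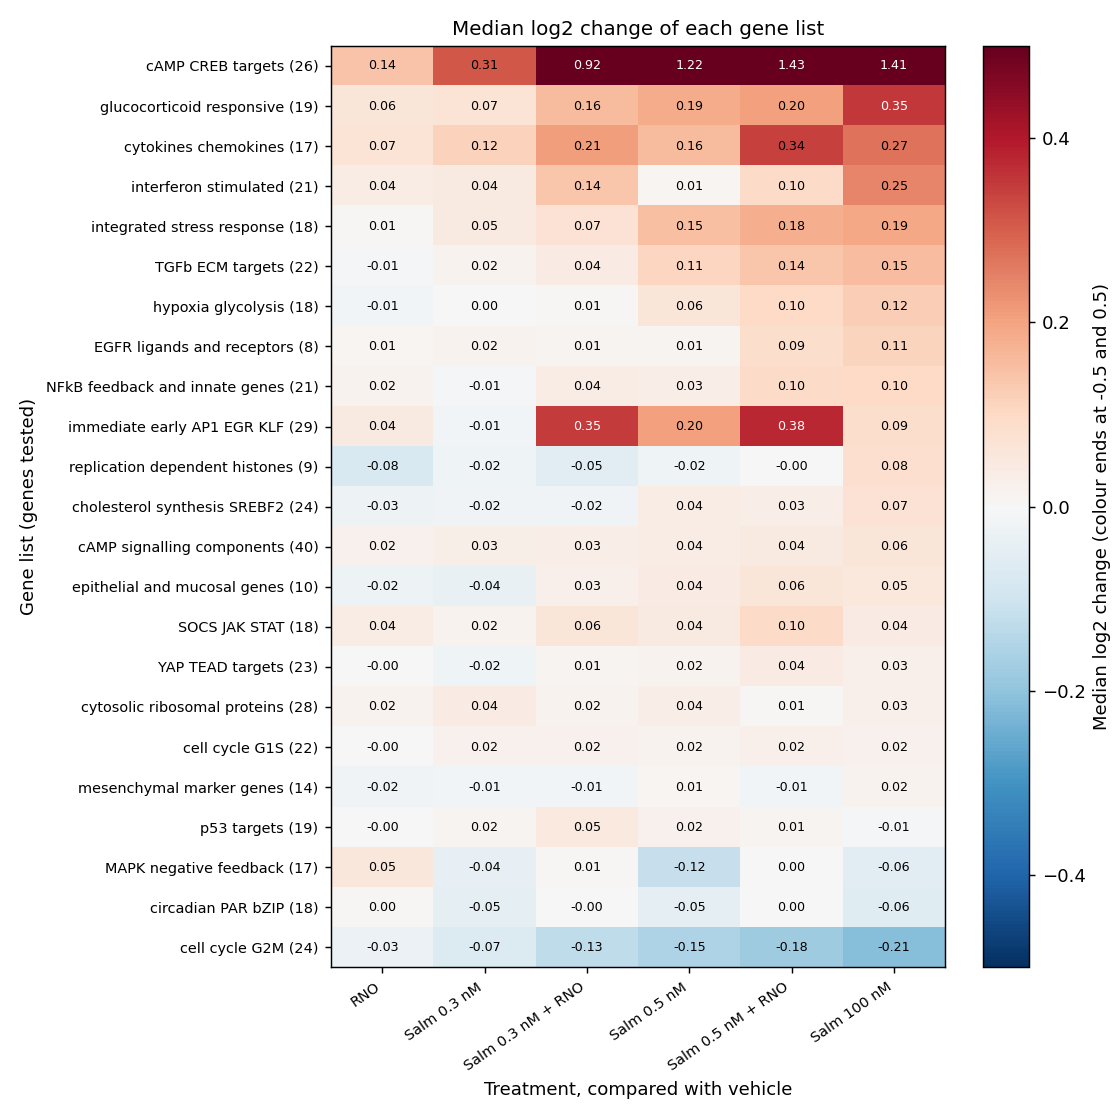
Heatmap of the median log2 change against vehicle of each of 23 gene lists (vertical axis) for the 6 treatments (horizontal axis), with colours ending at -0.5 and 0.5. The CREB targets had a median of 0.14 with RNO and 1.41 at 100 nM salmeterol.

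What RNO added to salmeterol was tested within each concentration. Added to 0.3 nM, RNO raised NR4A3 from 8.61 ± 0.959 to 29.1 ± 4.54 TPM (1.64 ± 0.12, adjusted p = 5.15e-09), NR4A2 from 5.32 ± 1.49 to 17.4 ± 3.76 TPM (1.55 ± 0.17, adjusted p = 5.86e-06) and IL6 from 8.43 ± 1.68 to 23.5 ± 7.23 TPM (1.34 ± 0.22, adjusted p = 0.000791). SGK1 (1.24 ± 0.19), NR4A1 (0.92 ± 0.12), IL11 (0.87 ± 0.17), DUSP1 (0.81 ± 0.13), PDE4D (0.72 ± 0.07), SLC2A3 (0.65 ± 0.064), PER1 (0.64 ± 0.11), AREG (0.63 ± 0.11) and ATF3 (0.58 ± 0.095) rose as well. RGS2 rose by 1.29 ± 0.20, a call lost when only the groups compared were fitted (adjusted p = 0.0505; 3.02e-06 to 0.0505 over all alternatives). The centromere chaperone gene HJURP (-0.23 ± 0.037) and the spindle gene PSRC1 (-0.20 ± 0.038) fell. CRISPLD2 (0.66 ± 0.089, adjusted p = 4.02e-05) and FOSB (0.69 ± 0.083, adjusted p = 1.05e-05) passed only with the block. In total 112 genes rose and 7 fell (94.1% higher), 7 of them at least 2-fold; with the block 598 rose and 311 fell (65.8% higher). RNO moved CREB targets at 0.3 nM: of 26, 14 rose and 0 fell (19 and 0 adjusted over the list alone), with a median log2 change of 0.60, camera up with adjusted p = 1.64e-41. Of 19 glucocorticoid-responsive genes, 5 rose and 0 fell (7 and 0 adjusted over the list alone, 9 and 0 with the replicate block), with a median log2 change of 0.17, camera up with adjusted p = 4.04e-09. Of 29 immediate early genes, 6 rose and 0 fell (11 and 1 adjusted over the list alone, 14 and 1 with the replicate block), among them NR4A1 (0.92), ATF3 (0.58) and MAFK (0.32), with a median log2 change of 0.23, camera up with adjusted p = 5.95e-09, adjusted p = 0.0913 with an estimated correlation. Of all 24 G2/M genes, 0 passed the limma test (6 at an unadjusted p under 0.05, 0 higher and 1 lower adjusted over the list alone, 0 and 9 with the replicate block), with a median log2 change of -0.054, camera down with adjusted p = 2.2e-06.

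Added to 0.5 nM, RNO raised 1 gene and lowered 0. It was SLC2A3 (0.39 ± 0.064, adjusted p = 0.033), which lost its call without any one of Salm0.5 replicate 3 or Salm0.5_RNO replicate 1, 2 or 3 (adjusted p from 0.0675 to 0.157) and when only the groups compared were fitted (adjusted p = 1; 0.00119 to 1 over all alternatives). The count was 0 without Salm0.5 replicate 3 or without Salm0.5_RNO replicate 1, 2 or 3, and 2 without Salm0.5 replicate 1 or 2. At an unadjusted p under 0.05 there were 552 genes. With the block 187 rose and 23 fell (100% higher without it, 89.05% with it), among them NR4A3 (0.55 ± 0.12, adjusted p = 0.0181), NR4A2 (0.59 ± 0.12, adjusted p = 0.0164), IL6 (0.69 ± 0.16, adjusted p = 0.0347) and DUSP1 (0.47 ± 0.078, adjusted p = 0.00347). Among 26 CREB targets, 0 passed the limma test (17 at an unadjusted p under 0.05, 11 higher and 0 lower adjusted over the list alone, 15 and 0 with the replicate block), with a median log2 change of 0.30, camera up with adjusted p = 4.28e-25. Of 18 stress response genes, 0 passed the limma test (2 at an unadjusted p under 0.05, 2 higher and 0 lower adjusted over the list alone, 2 and 0 with the replicate block), with a median log2 change of 0.041, camera up with adjusted p = 0.000269. Of 17 MAPK feedback genes, 0 passed the limma test (4 at an unadjusted p under 0.05, 2 higher and 0 lower adjusted over the list alone, 4 and 0 with the replicate block), with a median log2 change of 0.10, camera up with adjusted p = 1.38e-05.

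Whether the combinations departed from the sum of the single effects on log2(TPM + 1) was tested as an interaction. That scale understates the effect of RNO alone for genes below 1 TPM in vehicle, as NR4A3 and NR4A2 were. Part of a surplus over the sum can come from the scale for such genes. At 0.3 nM, limma without a block called 0 genes, with 452 at an unadjusted p under 0.05; leaving out RNO replicate 4 or Salm0.3_RNO replicate 2 gave 2. With the block 51 genes lay above the sum and 12 below; without Salm0.3 replicate 4 these were 19 and 3. Above it were IL6 (1.21 ± 0.23, adjusted p = 0.023), RGS2 (1.09 ± 0.20, adjusted p = 0.014), NR4A2 (1.09 ± 0.17, adjusted p = 0.0107), FOSB (0.67 ± 0.12, adjusted p = 0.014) and PER1 (0.42 ± 0.092, adjusted p = 0.0418). NR4A3 was at 0.72 ± 0.17 and passed neither with the block (adjusted p = 0.054) nor without it (adjusted p = 0.305). In TPM, the means of NR4A3 given above rose by about the same factor with RNO alone as with RNO added to 0.3 nM. The surplus of NR4A3 can thus come wholly from the scale. An entry that joins LOC102724428 and SIK1 was also above the sum (0.72, adjusted p = 0.02), and the table does not say which of these loci its reads came from. Below it were the cyclin gene CCNG2 (-0.24 ± 0.043, adjusted p = 0.014) and the MYC antagonist MXD3 (-0.21 ± 0.047, adjusted p = 0.0473). Without that library PER1 (0.41 ± 0.098, adjusted p = 0.0868), MXD3 (-0.22 ± 0.05, adjusted p = 0.0812) and the joined entry (0.68 ± 0.14, adjusted p = 0.051) no longer passed at about the same changes, and IL6, RGS2, NR4A2, FOSB and CCNG2 did (highest adjusted p 0.0433). CCNG2, MXD3 and the joined entry were chosen after their values were seen. At 0.5 nM limma called 0 genes both without and with the block (255 and 1017 at an unadjusted p under 0.05), and IL6 (0.56 ± 0.31), NR4A2 (0.13 ± 0.24) and NR4A3 (-0.38 ± 0.17) did not pass. Of 26 CREB targets in the interaction at 0.3 nM, 0 passed the limma test (13 at an unadjusted p under 0.05, 11 higher and 0 lower adjusted over the list alone, 9 and 0 with the replicate block), with a median log2 change of 0.38, camera up with adjusted p = 8.78e-23. Of the same 26 genes in the interaction at 0.5 nM, 0 passed the limma test (4 at an unadjusted p under 0.05, 0 higher and 0 lower adjusted over the list alone), with a median log2 change of 0.12, camera up with adjusted p = 0.00954, adjusted p = 0.635 with an estimated correlation.

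A held-out response index put each effect on the scale of the 100 nM response. For each replicate, genes that 100 nM salmeterol changed in the other 3 replicates with the block (3660 to 4017 genes) were taken, and the effect in that replicate was regressed through 0 on their mean change. Changes were on log2(TPM + 1), which understates the effect of RNO alone for genes below 1 TPM in vehicle, NR4A3 among them. Against vehicle the index was 0.0915 ± 0.0154 for RNO (mean ± SD, n = 4), 0.32 ± 0.0402 at 0.3 nM, 0.59 ± 0.0435 at 0.3 nM with RNO, 0.771 ± 0.0907 at 0.5 nM, 0.892 ± 0.0443 at 0.5 nM with RNO and 0.939 ± 0.0508 at 100 nM. RNO added 0.269 ± 0.0413 at 0.3 nM and 0.12 ± 0.0673 at 0.5 nM. The addition at 0.3 nM was larger than the effect of RNO alone by 0.178 in a two-sided exact permutation test (p = 0.0286, the smallest that 4 against 4 can give; adjusted over 3 tests 0.0429; 4 of 4 replicates higher). It was larger than the addition at 0.5 nM by 0.149 (exact p = 0.0286, adjusted p = 0.0429, 4 of 4 replicates). That permutation ignores that the numbers pair the samples: sign flips over the 4 replicates, which keep the pairs, gave p = 0.125 for both differences (adjusted p = 0.188), the smallest that 4 pairs can give, so neither passed. The addition at 0.5 nM differed from the effect of RNO alone by 0.0288 (exact p = 0.686, adjusted p = 0.686, 3 of 4 replicates higher). Per gene, the addition at 0.3 nM minus that at 0.5 nM passed for NR4A3 alone without a block (1.10 ± 0.17, adjusted p = 0.00948; 250 genes at an unadjusted p under 0.05). With the block ZNF331 passed too (0.81 ± 0.14, adjusted p = 0.0392; 817 genes at an unadjusted p under 0.05). Without Salm0.3 replicate 4 and with the block limma called 0 genes (731 at an unadjusted p under 0.05; NR4A3 1.04 ± 0.17, adjusted p = 0.0802).

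**Figure D4:**
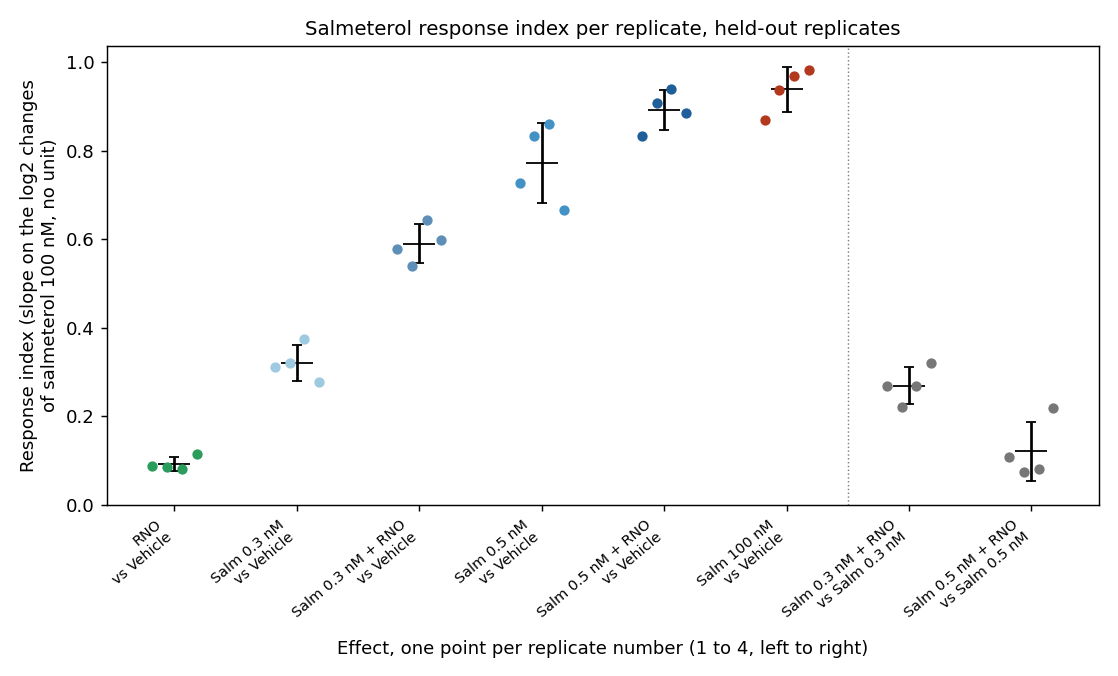
Held-out salmeterol response index (vertical axis, no unit, 1 for a change equal to the mean 100 nM response) of each effect (horizontal axis) in the 4 replicates (points), with the mean and SD (bars). RNO added 0.269 to 0.3 nM salmeterol and 0.12 to 0.5 nM on average.

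What salmeterol added to RNO was tested against RNO alone. With 0.3 nM, NR4A3 (3.29 ± 0.12), NR4A2 (3.00 ± 0.17), ZNF331 (2.80 ± 0.12), LINC00473 (2.45 ± 0.14), RGS2 (2.29 ± 0.20), IL6 (2.27 ± 0.22) and SGK1 (2.25 ± 0.19) rose (highest adjusted p 4.77e-08), and FOSL1 (-0.97 ± 0.17) and JUN (-0.64 ± 0.085) fell. In total 298 genes rose and 147 fell (67.0% higher), and with the block 807 and 663 (54.9% higher). With 0.5 nM, NR4A3 (4.48 ± 0.12), NR4A2 (4.10 ± 0.17), ZNF331 (3.72 ± 0.12), IL6 (3.68 ± 0.22) and SGK1 (3.33 ± 0.19) rose and FOSL1 (-1.58), RGS4 (-1.51), KLF10 (-1.32), EGR1 (-1.20) and TXNIP (-1.09) fell, among 841 increases and 692 decreases (1919 and 1755 with the block). The sterol gene INSIG1 (0.48) rose with 0.5 nM. With 0.3 nM, of 26 CREB targets 17 rose and 0 fell (21 and 0 adjusted over the list alone), with a median log2 change of 0.76, camera up with adjusted p = 5.45e-47. With 0.5 nM, of the same 26 genes 21 rose and 0 fell (22 and 0 adjusted over the list alone), with a median log2 change of 1.23, camera up with adjusted p = 4.8e-40.

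The combinations were then set against maximal salmeterol. With 0.3 nM and RNO, IL6 was lower than at 100 nM (-1.48 ± 0.22, adjusted p = 7.34e-05; 23.5 ± 7.23 against 65.5 ± 11.1 TPM), as were CRISPLD2 (-1.20 ± 0.19), NR4A3 (-1.09 ± 0.12), SGK1 (-1.07 ± 0.19), the immunoregulatory membrane protein gene CD200, NR4A2 (-0.87), PDE4D (-0.71) and AREG (-0.64). EGR1 (1.07 ± 0.22), TXNIP (1.00 ± 0.11) and FOSL1 (0.98 ± 0.17), genes that 100 nM lowered, were higher. In total 227 genes were higher and 378 lower; with the block 1094 and 1325. Against 100 nM, of 26 CREB targets 0 rose and 11 fell (1 and 16 adjusted over the list alone, 1 and 19 with the replicate block), with a median log2 change of -0.38, camera down with adjusted p = 2e-15. Of 18 hypoxia and glycolysis genes, 0 rose and 7 fell (0 and 8 adjusted over the list alone, 0 and 11 with the replicate block), including SLC2A3 (-0.62), SLC2A1 (-0.25) and PFKFB3 (-0.40), with a median log2 change of -0.12, camera down with adjusted p = 1.03e-08. Of 24 mitotic genes, 5 rose and 0 fell (8 and 0 adjusted over the list alone, 19 and 0 with the replicate block), with a median log2 change of 0.096, camera up with adjusted p = 1.03e-08.

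With 0.5 nM and RNO, limma without a block called 0 genes against 100 nM salmeterol (490 at an unadjusted p under 0.05), and 0 whichever library was left out. NR4A3 differed by 0.094 ± 0.12, IL6 by -0.08 ± 0.22, PDE4D by -0.11 ± 0.07 and CRISPLD2 by -0.23 ± 0.19. With the block 83 genes were higher and 42 lower. Higher were EGR1 (0.65 ± 0.10, adjusted p = 0.00274), the matrix protein gene CTGF (0.35 ± 0.039, adjusted p = 0.000137) and the cytokine gene LIF (0.37 ± 0.062, adjusted p = 0.00452); lower were the calcium-regulated transcription factor gene NFATC2 (-0.42 ± 0.048, adjusted p = 0.000137) and ITPKB (-0.31 ± 0.066, adjusted p = 0.0271). For EGR1, higher means a smaller fall against vehicle, by -1.23 with 0.5 nM and RNO and by -1.88 at 100 nM. CTGF (0.53 and 0.19) and LIF (0.43 and 0.062) instead had larger positive changes with the combination. NFATC2 and ITPKB were chosen after their values were seen. Of 29 immediate early genes, 0 passed the limma test (8 at an unadjusted p under 0.05, 0 higher and 0 lower adjusted over the list alone, 6 and 0 with the replicate block), with a median log2 change of 0.12, camera up with adjusted p = 9.98e-06, adjusted p = 0.378 with an estimated correlation. In the last comparison, of 26 CREB targets 0 passed the limma test (4 at an unadjusted p under 0.05, 0 higher and 0 lower adjusted over the list alone, 2 and 0 with the replicate block), with a median log2 change of 0.12, camera up with adjusted p = 0.0063, adjusted p = 0.623 with an estimated correlation.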

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

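The index test of the fourth library at 0.3 nM salmeterol and the test of mir-1281 across concentrations were chosen only after their results had been seen, as were the sign flips of the index differences, and the fits without that library were chosen after the data had been examined. A screen of 127 groups of 4 values found 7 with an outlying library, where chance alone gives about 6.35. NR4A2 was high in RNO replicate 1 (1.607 TPM against 1.137 to 1.191) and CEBPD in Salm0.5 replicate 4 (127.5 against 115.6 to 116.5). With 0.3 nM salmeterol and RNO, FOSL1 was low in replicate 3 (60.53 TPM against 75.12 to 77.31), mir-1281 in replicate 3 (23.41 against 57.83 to 58.66) and ZNF331 in replicate 2 (43.32 against 61.12 to 63.62).

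Salm0.3 replicate 4 had 303 genes at 0, against 9 to 14 in the other libraries of its group. Of these genes 253 were above 0 in all other 27 libraries, the median of their mean TPM there was 0.224, and all 22 with a mean above 10 TPM were small RNA. A wrong group label is argued against by its response index of 0.2775, which lay outside the 0.3107 to 0.3743 of the other replicates by less than their range. Lower depth may explain the zeros: its deviation from its group, relative to the other groups, was 1.68 times at 0.1 to 1 TPM, 1.38 at 1 to 10, 1.33 at 10 to 100 and 1.36 above 100 TPM. This met the condition set beforehand, but the excess did not keep falling above 1 TPM and depth cannot be read from TPM, so it stays open. No biological explanation was tested.

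RNO added more to 0.3 nM than to 0.5 nM salmeterol, by 0.1488 of the response index, and more to 0.3 nM than it did alone, by 0.1776, higher in 4 of 4 replicates in both, though with the replicates kept paired neither difference passed an exact permutation test by sign flips (p = 0.125, the smallest that 4 pairs can give). As the whole cause of the index difference, the fourth library at 0.3 nM is argued against, since replicates 1 to 3 gave 0.1645 (SD 0.022, lowest 0.1454) and replicate 4 gave 0.102. A further test, written after the data had been examined but before its result was seen, was the count of genes in the contrast of both additions with the block, which went from 2 to 0 without that library, as a dependence on it would have it; NR4A3 went from 1.10 ± 0.17 (adjusted p = 0.018) to 1.04 ± 0.17 (adjusted p = 0.0802) and ZNF331 from 0.81 ± 0.14 (adjusted p = 0.0392) to 0.77 ± 0.14 (adjusted p = 0.163), so the calls ended with small losses of fold and gains of SE near the threshold. A ceiling at the maximal response stays open and cannot be told apart from a true difference, as the index of 0.5 nM with RNO lay below that of 100 nM by more than 1 SD (-0.0472, SD 0.0335), where the ceiling called for a difference within 1 SD and its absence for one above by more. Without RNO, the mean index at 0.5 nM was already 0.8216 of that at 100 nM, against 0.3412 at 0.3 nM. This left less room below the maximal response for an addition at 0.5 nM. Over 100 reshufflings for that contrast 6 gave at least the 1 gene of the real split without the block and the highest other gave 396. The reshufflings exchange libraries between concentrations, whose effects stay in the shuffled contrast, so they are no value of no change and decide nothing about chance. Which grouping gave the count of 396, and why, was not tested.

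At 0.3 nM salmeterol, mir-1281 had the largest fitted increase, with 177 TPM in replicate 4 against 57.25 to 69.24 in the others, and Vehicle replicate 3 was listed at 0. Few reads on a short entry may explain it: its residual SD of 1.07 was at the percentile 100 of 2978 other entries of like TPM, whose median was 0.061. Over 186 small RNA entries the median residual SD was 0.471, against 0.0793 for the other genes. A response that follows salmeterol cannot be told apart from it, since the fitted change at 100 nM was 1.84, neither as large as at 0.3 nM nor far below it, and this keeps it open. With RNO alone, without salmeterol, the fitted change was 1.82 ± 0.71, close to that at 100 nM. All these changes are against the same vehicle libraries, including the one listed at 0.

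Other splits of the same libraries were fitted without the block for each count. For 12 of the 14 pair comparisons the real split alone (1 of 35) gave as many genes. That is the smallest share 35 splits can give, and it was not adjusted over the comparisons. Most of these splits also break the pairing by number, so they do not exclude chance. Against vehicle, the highest other split gave 0 genes for RNO (real 5), 0 for Salm0.3 (245), 1 for Salm0.5 (1249), 2 for Salm100 (2318), 1 for Salm0.3_RNO (670) and 0 for Salm0.5_RNO (1886). It gave 1 for RNO added to 0.3 nM (119), and 0 and 1 for 0.3 and 0.5 nM added to RNO (445 and 1533). It gave 0 for Salm0.3_RNO against Salm100 (605), 1 for Salm0.5 against Salm0.3 (524) and 0 for Salm100 against Salm0.5 (12). For RNO added to 0.5 nM, 4 of 35 splits gave at least the real count of 1 and the highest other gave 2, so chance could not be excluded. Where the real count was 0 every split must give at least as many, so the 35 of 35 for Salm0.5_RNO against Salm100 (highest other 0) and the 100 of 100 for the interactions at 0.3 and 0.5 nM (highest others 3 and 1) decide nothing about chance. No splits were fitted for the counts with the block. Of the 8 splits that part every same-number pair, the other 7 gave at most 1 gene in every pair comparison; these 8 keep the pairing and are too few for a share under 0.05.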

How the results depend on the processing

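The block without Salm0.3 replicate 4, and the list tests without that library, and leaving out libraries for SLC2A3 from 0.5 to 100 nM, were chosen after the data were seen. No named gene that was called in the reported fit or in a setting reversed its direction in that setting. Changes of sign among genes called in neither were not counted. Named gene calls lost and newly passed were 0 and 143 with the replicate block, 1 and 131 with the block without Salm0.3 replicate 4, 24 and 1 without the filter, 55 and 4 with only the groups compared, 13 and 1 with a pseudocount of 0.1, 8 and 3 with a pseudocount of 5, 9 and 0 with robust limma, 5 and 4 with size-factor scaling, and 282 and 27 over all fits that left out a library. List calls lost and gained were 99 and 0 with an estimated correlation, 60 and 14 with fry, 13 and 27 with the block, and 3 and 5 without Salm0.3 replicate 4.

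With the replicate block the counts became 24 for RNO, 1241 for Salm0.3, 3215 for Salm0.5, 4601 for Salm100, 2127 for Salm0.3_RNO and 4151 for Salm0.5_RNO against vehicle, 909 and 210 for RNO added to 0.3 and 0.5 nM, 1470 and 3674 for 0.3 and 0.5 nM added to RNO, 2419 and 125 for the combinations against Salm100, 1855 for Salm0.5 against Salm0.3, 490 for Salm100 against Salm0.5 and 63 for the interaction at 0.3 nM; at 0.5 nM it stayed at 0. The block without Salm0.3 replicate 4 gave, in the same order, 25, 958, 3397, 4796, 2295, 4377, 684, 243, 1588, 3876, 2599, 175, 1457, 530 and 22. The block removes variance shared by libraries with the same number, and changed no other call of a named gene than the 143 counted above, only some of which are printed.

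With only the groups compared in the fit, the counts were 1 for RNO and 163 for Salm0.3 against vehicle, 70 and 0 for RNO added to 0.3 and 0.5 nM, 352 and 1 for the combinations against Salm100, 239 for Salm0.5 against Salm0.3, 0 for Salm100 against Salm0.5 and 1 for the interaction at 0.3 nM; these fits have fewer libraries. A pseudocount of 5 gave 3 genes for RNO and 3 for the interaction at 0.3 nM, and a pseudocount of 0.1 or no filter gave 2 for Salm100 against Salm0.5. Robust limma and size-factor scaling each gave 1 for the interaction at 0.3 nM. Leaving out single libraries gave 4 to 8 for RNO, 0 to 2 for RNO added to 0.5 nM, 0 to 23 for Salm100 against Salm0.5 and 0 to 2 for the interaction at 0.3 nM. For the pseudocounts, the filter, robust limma and the scaling the cause was not tested. All other counts stayed within 1.5 times. Since TPM keep no counts, it cannot be said which changes of low genes lie within counting error.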

Other observations

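The test of mitotic genes across concentrations was chosen after its result had been seen. Over the 24 G2/M genes, the mean log2 change per replicate against vehicle was -0.0312 ± 0.0111 for RNO (mean ± SD, n = 4), -0.0901 ± 0.0129 for 0.3 nM salmeterol, -0.149 ± 0.0121 for 0.3 nM with RNO, -0.196 ± 0.0101 for 0.5 nM, -0.199 ± 0.00713 for 0.5 nM with RNO and -0.244 ± 0.0335 for 100 nM. In 4 of 4 replicates the fall at 0.5 and 100 nM exceeded that at 0.3 nM, so the fall of mitotic transcripts within 2 h may scale with the salmeterol concentration. RNO added to 0.5 nM left the fall nearly the same (-0.199 against -0.196), although RNO raised the mean response index there. Whether fewer cells divided was not measured.

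Genes that RNO changed may be ones that salmeterol changes anyway. All comparisons come from 1 fit with a shared estimate of the spread per gene. The numbers expected for independent lists may therefore be too low here, even where no library is shared. The comparison of RNO added to 0.3 nM shares no library with 100 nM salmeterol against vehicle. Of its 112 increases without the block, 109 were among the 1110 increases at 100 nM, where independent lists would share 9.55 (11.4 times as many), and of its 7 decreases 5 were among the 1208 decreases (0.65 expected). None of either went the opposite way (0 genes). With the block the overlap was weaker: 498 of 598 increases were shared (4.84 times as many as independent lists) and 155 of 311 decreases (2.75 times), and 10 and 17 went the opposite way. All 5 genes that RNO raised alone were among the 388 that were higher at 0.5 than at 0.3 nM (0.149 expected), a comparison that again shares no library. With the block 22 of 24 were among 1067 (1.97 expected), and the other two were FLT3LG and IRS1, chosen after their values were seen.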
